A study of Mus musculus with 3 samples.

How the data were processed

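The series holds RNA from the CA1 field of the hippocampus of young male C57BL/6J mice, measured on 3 single-colour oligonucleotide arrays. All 3 samples belong to 1 group. Per the labels, mice spent 2 min in an unfamiliar chamber, then received a floor shock of 0.5 mA for 1 s. That sequence was given 3 times in all, and RNA was taken 1 h after the last shock. The title numbers the samples 1 to 3, and these numbers are used below as replicates 1, 2 and 3. The labels do not say whether a replicate is 1 animal or a pool, so the spread given here is that between these samples and may be partly technical. No untreated, context-only or shock-only sample is analysed here, so no change caused by the treatment can be computed.

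The only file is a deposited table of intensity values, 1 row per probe set and 1 column per array. The software, the background correction and the normalization behind it are not given in the sources used here. The deposited intensities are linear, all above 0 and written with 1 decimal. Their mean, after leaving out 2% of probe sets at either end, is 500.3 on replicates 1, 2 and 3 alike, as it would be for arrays scaled to a common level. No detection call was used here. The number of arrays limits the precision of every mean. The file holds no read counts, so no counting interval applies.

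The table has 12488 probe sets, of which 66 are array controls. Gene names come from the platform annotation, matched through gene IDs to the gene table of the mouse assembly GRCm38.p6. One gene symbol was found for 10833 probe sets, several for 396 and none for 1193. No name was taken from a probe set with several symbols. Of the probe sets with 1 symbol, 10817 had a gene ID in the gene table, and 0 symbols changed. They cover 8251 genes. For a gene with several probe sets, the one with the highest mean among those above background was used. No coordinates are printed, because the deposited values name no genome build.

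A background floor was set per array at the highest of 15 control probe sets for bacterial transcripts that are not usually added at hybridisation. It was 101.8 on replicate 1, 64 on replicate 2 and 64 on replicate 3. A probe set counted as above background when it exceeded the floor on all 3 arrays, and a gene when any of its probe sets did. A gene below the floor was not well above background, which does not show that its transcript is absent. Another 15 control probe sets read the opposite strand of abundant or added control transcripts. The highest of these was 678.5, 641 and 563.6 on replicates 1, 2 and 3, and it served as a much stricter floor, chosen after seeing the data. The floor on replicate 1 drops probe sets that are low there more readily than on the other arrays. For this reason 2 further selections were added after seeing the data. The first sets the floor at 101.8 on all arrays, and the other takes probe sets whose mean log2 signal over the arrays exceeds the mean log2 floor.

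Levels are given as mean signal ± SD over the 3 arrays (n = 3). For the spread, values were taken as log2 with no pseudocount, since none is 0. Each probe set was expressed as its deviation from its own mean, and each array was centred on its median deviation. That median was 0.02, -0.003 and -0.005 on replicates 1, 2 and 3. To relate spread to brightness, probe sets above background were split by mean signal into 5 classes of equal size. The brightness of a probe set depends on its sequence, so levels of different genes are not ranked against each other.

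Before the data were examined, 23 gene lists were fixed (immediate-early genes, glucocorticoid-responsive genes, glutamate receptors, plasticity kinases, the NF-kB family, GABA and interneuron genes, synaptic vesicle genes, heat shock genes, housekeeping genes, ribosomal proteins, oxidative phosphorylation, proteasome, sex-linked genes, and markers of CA1, CA2 and CA3, dentate gyrus, choroid plexus, striatum, thalamus and cortex, oligodendrocytes, astrocytes, microglia, endothelium and pericytes, and blood cells). The floor, the measures and the processing alternatives were fixed then too, except those named as chosen later. For the 21 lists with at least 3 genes above background, 2 values were computed: the median SD of the members, and the joint shift, which is the range over the arrays of the members' mean deviation. Each was set against 10000 random lists of the same size, drawn gene by gene from the same of 20 brightness bins. A list was called apart in spread outside the percentiles 2.5 to 97.5, and apart in joint shift at the 95th percentile or above. Genes are not replicates, so these percentiles describe the 3 arrays and are not p-values. For lists of unrelated genes, chance alone would put 1.05 of the 21 lists apart on either measure.

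The procedure was tested on simulated arrays made from the same 5515 genes, with 100 simulated lists per setting. In these simulations the arrays were shuffled gene by gene, so genes varied independently apart from the added shift. The rates hold for such genes only, not for lists whose genes vary together. With lists of 8 genes it called 1% without a shift, 49% at a shift of 0.3 and 100% at a shift of 1, on the log2 scale. With lists of 20 genes it called 3%, 88% and 100%. With lists of 60 genes it called 5%, 100% and 100%, and 53% at a shift of 0.1.

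Genes are named by a rule fixed before the data were examined. It takes 26 preset genes where measured, the 3 members with the largest and the 2 with the smallest SD of each list called apart, the 15 genes with the largest SD, and the sex-linked genes. Of the preset genes, Arc, Nfkb1 and Grin1 had no probe set of their own in the annotation and are not analysed here, and 1 other is not reported here. Genes named outside this rule are marked as chosen after their values were seen. The alternatives tried were other floors, no centring, quantile normalization, the mean of all probe sets of a gene, stricter and looser treatment of dim probe sets, 10 or 40 brightness bins, and leaving out each replicate. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.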

Results

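Gene expression was measured in the CA1 field of the mouse hippocampus 1 h after contextual fear conditioning, a training in which an unfamiliar place is paired with foot shock. The 3 replicate samples form a single group. The data therefore give the expression state of CA1 at that time and its variation between replicates, and they hold no comparison with untrained animals. Of the 12422 probe sets other than controls, 7173 were above background on all 3 arrays, a floor that 13 of 15 opposite-strand control probe sets also exceeded. The share above background was 63.3% on replicate 1, 69.6% on replicate 2 and 69.5% on replicate 3. Across these 7173 probe sets, which are not independent replicates, Pearson's r of the log2 signals was 0.965 between replicates 1 and 2, 0.964 between replicates 1 and 3, and 0.970 between replicates 2 and 3. The median SD over the replicates was 0.19 on the log2 scale, which is 1.14-fold. It was 0.35 in the dimmest of 5 brightness classes and 0.11 in the brightest.

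The first question the design raises is which activity-regulated genes gave signal above background in CA1 at 1 h. Of the 42 immediate-early genes measured, 34 were above background, against 5515 of all 8251 genes measured. Fos, which encodes a subunit of the transcription factor AP-1, had a mean signal of 817 ± 226 (SD, n = 3), with 638.5, 742.8 and 1070.9 on replicates 1, 2 and 3. Its relative Fosb had 727 ± 93.2, and Junb, another AP-1 subunit, had 537 ± 30.8. Egr1, a zinc finger transcription factor induced by synaptic activity, had 2858 ± 301. Nr4a1, an orphan nuclear receptor, had 1032 ± 102. Bdnf, a secreted neurotrophin, had 2586 ± 464, and Dusp1, a phosphatase that acts on MAP kinases, had 775 ± 176. Against the strictest floor, that of the sense-strand controls, 8 of these 42 genes were above background on all 3 arrays, and among the preset genes those were Egr1, Nr4a1 and Bdnf. Of all 12422 probe sets other than controls, 2539 were above that floor, a share of probe sets and not of genes. These counts were not tested against other genes.

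The probe sets of a gene did not always agree, and averaging them moved the level by more than its SD for 19 of the 22 named genes with several. A second Fos probe set had 36 ± 27.7 and a second Egr1 probe set 114 ± 69.5, and neither was above background on all 3 arrays. A second Junb probe set was above background with 283 ± 107 and ranged from 163.6 on replicate 1 to 371.4 on replicate 3, where the brighter one ranged from 506.8 to 568.3. Neither Homer1 probe set was above background on all 3 arrays, and the brighter one, with 79.7 ± 21.9, was above it on replicates 2 and 3. As a list, the immediate-early genes lay 0.07 above their own mean on replicate 3 and 0.06 below it on replicate 1, on the log2 scale. Of the 34 genes, 18 were higher on replicate 3 than on replicate 1. The list's joint shift of 0.13 was at percentile 84.8 of matched random lists, and the median SD of 0.21 was at percentile 85.1, so neither passed its threshold. The joint shift passed it without replicate 2, at percentile 96.9, with the floor at the array median, at 95.05, and with all values raised to the floor, at 96.1. Egr2 and Inhba, chosen after their values were seen, went opposite ways. Egr2 had 195.6, 308.9 and 512.1 on replicates 1, 2 and 3, and Inhba had 297.2, 208.7 and 157.1.

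**Figure D1:**
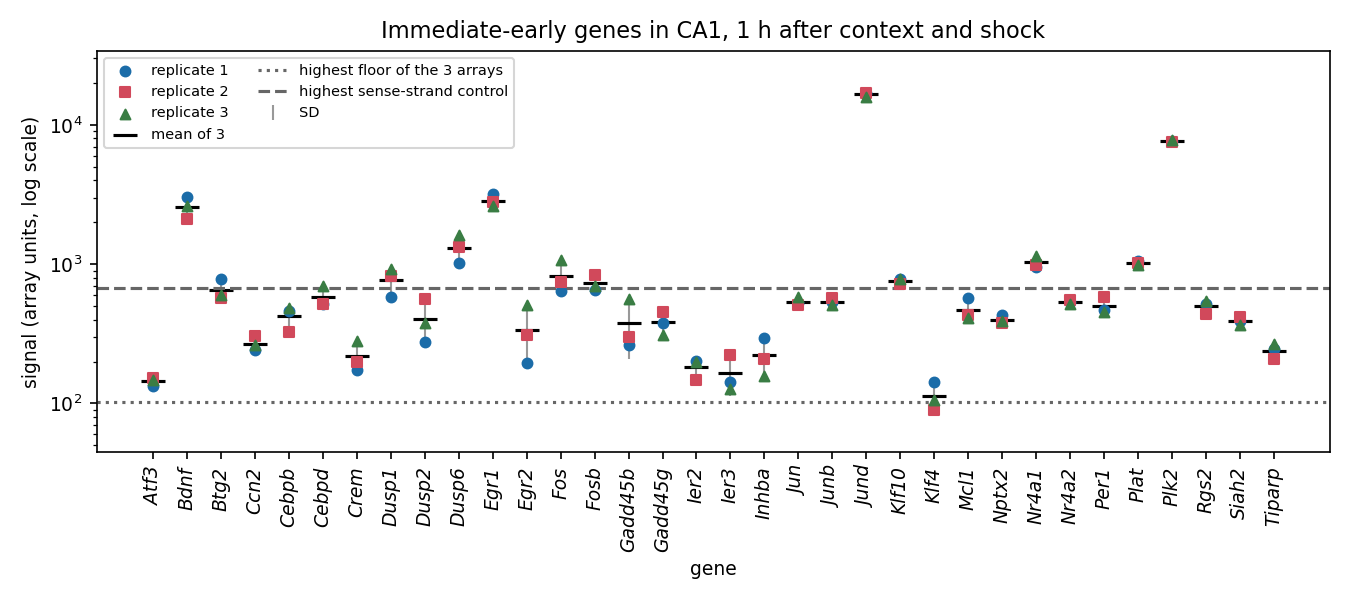
Signal of the 34 immediate-early genes above background (x axis) on a log scale in array units (y axis), with 1 point per replicate, a bar for the mean, a line for the SD (n = 3), and dotted and dashed lines for the 2 background floors at their highest over the arrays. Egr1 and Bdnf lie above the dashed line on every replicate, and Fos ranges from 638.5 to 1070.9.

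Genes that respond to glucocorticoids, the hormones released by stress, were measured too. Of 17, 14 were above background and 9 were above the strictest floor. Fkbp5, a co-chaperone of the glucocorticoid receptor, had 893 ± 49.5. Sgk1, a serum- and glucocorticoid-regulated kinase, had 2096 ± 283, and Per1, a clock gene that belongs to this list and to the immediate-early list, had 504 ± 70.3. The list's joint shift of 0.09 was at percentile 38.1 and its median SD of 0.17 at percentile 77.4.

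Genes of synaptic plasticity did not stand apart from matched random lists in joint shift. Of 17 glutamate receptor and scaffold genes measured, 12 were above background, with Gria1, an AMPA receptor subunit, at 5166 ± 611. Its second probe set had 640 ± 49.1. Of 24 kinase and signalling genes, 20 were above background, but both probe sets of Camk2a, a kinase abundant in forebrain neurons, were not, the brighter one with 45.4 ± 23.7. In the NF-kB family, a group of inducible transcription factors and their inhibitors, 7 of 14 genes were above background. Nfkbia, the inhibitor IkB-alpha, had 1050 ± 113 and a second probe set with 567 ± 26.8. Rel, the c-Rel subunit, was not well above background on any array, with 9.9 ± 5.2. The joint shifts of these 3 lists were at percentiles 86.6, 47.2 and 7.46 in the order given, and none passed the threshold. The glutamate receptor list passed it with the mean of all probe sets of a gene, at 96.1.

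Of the markers of cell types and fields, all 7 measured for CA1 pyramidal cells were above background and 5 were above the strictest floor. Wfs1, an endoplasmic reticulum protein used as a CA1 marker, had 1857 ± 20 and differed by 1.02-fold between the highest and lowest replicate. Markers of CA2 and CA3 were above background for 7 of 10 genes and above the strictest floor for 4, and markers of the dentate gyrus for 8 of 11 and for 2. Prox1, a transcription factor of dentate granule cells, was not well above background, with 37 ± 18.6. Of the genes used as markers of striatum, thalamus and cortex, 8 of 12 were above background, and 0 were above the strictest floor. Of the GABA and interneuron genes, 14 of 16 were above background and 10 were above the strictest floor. These counts were not tested against other genes, and 5515 of all 8251 genes measured were above background. At the strictest floor the share is known here for probe sets only, 2539 of the 12422 other than controls. Pvalb (parvalbumin) had 3467 ± 70 and Sst (somatostatin) had 11407 ± 738. A second Pvalb probe set had 255 ± 53.4. The joint shifts of these 5 lists were at percentiles 26.2, 67.5, 74.5, 73.1 and 9.13, and none passed the threshold. The dentate gyrus list passed it without replicate 1, at 95.6.

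All 16 measured astrocyte genes were above background, with Gfap, the glial intermediate filament, at 2299 ± 355. Their joint shift of 0.20 was at percentile 94.8, short of the threshold. It passed without centring, at 96.6, without replicate 2, at 97.9, with the strictest floor, at 97.3, and with 1 floor on all arrays, at 97.8. Without replicate 3 the astrocyte joint shift fell to 0.05, at 39.2, and with all values raised to the floor it was 0.20, at 9.12. Of 11 oligodendrocyte genes, 9 were above background, with Mbp, myelin basic protein, at 8545 ± 991. This list did pass the threshold for joint shift, with 0.30 at percentile 98.1. It lay 0.17 above its own mean on replicate 1 and 0.13 below on replicate 2, and 8 of the 9 genes were higher on replicate 1 than on replicate 2. The 9 endothelial and pericyte markers above background, of 16 measured, were all higher on replicate 1 than on replicate 2, with a joint shift of 0.29 at percentile 87.2. This depended on the floor, which was higher on replicate 1, and 5 of the 7 markers below it were higher on replicate 2 than on replicate 1. The joint shift was 0.17 with the floor at the 25th percentile, 0.07 at the median control, 0.08 with probe sets chosen by mean signal and 0.31 with 1 floor on all arrays, at percentiles 49.1, 6.27, 10.2 and 92.95. The latter 2 selections were added after seeing the data. Without replicate 1 the joint shift of the endothelial and pericyte markers was 0.02, at percentile 14.6, over 14 genes. Mag, a myelin adhesion glycoprotein, had 727.2 on replicate 1, 498.9 on replicate 2 and 464.7 on replicate 3. Cldn11, a tight junction protein of myelin, had 778.6, 597.8 and 670.7, and Ugt8a, an enzyme of myelin lipid synthesis, had 155.8, 82.9 and 102.9. Mog differed by 1.07-fold and Sox10 by 1.14-fold over the replicates. Dimmer second probe sets of Mag, with 151.3, 108.3 and 108.2, and of Cldn11, with 156.8, 85.3 and 104.8, were also highest on replicate 1, while that of Mbp was lowest there, with 681.4, 766 and 787.2. The second probe set of Sox10, not above background on all arrays, was lowest there too, with 82.7, 124.4 and 178.9. The oligodendrocyte call was lost without replicate 1, at percentile 60.1, without replicate 2, at 93.9, with the strictest floor, at 94.6, and with all values raised to the floor, at 13.2. It was also lost with the floor at the median control, at 86.7, and with probe sets chosen by mean signal, at 90.7. The joint shifts in these last settings, 0.32 and 0.31, were no smaller.

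Of the 21 lists tested, the choroid plexus markers differed most between the replicates. Ttr, which encodes transthyretin, the main secreted protein of the choroid plexus, had 1016.6 on replicate 1, 4441.6 on replicate 2 and 161.4 on replicate 3, a 27.5-fold range. Igf2, a growth factor also made by choroid plexus and meninges, had 2139.4, 2854 and 1273. Of 13 measured markers, 8 were above background, and all 8 were higher on replicate 2 than on replicate 3. Lbp had 310.5, 299.6 and 187.2, and Folr1, a folate receptor, had 225.9, 209.5 and 179. Cox8b, a subunit of cytochrome oxidase that is also in the oxidative phosphorylation list, was lowest on replicate 1, with 152.2, against 341.2 on replicate 2 and 326.5 on replicate 3. Its second probe set, not above background on all arrays, had 105.1, 55.3 and 61.3. Of the 5 markers not above background on all arrays, chosen after their values were seen, Slc4a5 (17.1, 70.1 and 3), Ace (73.9, 306.9 and 137.9) and Cldn2 (24.6, 34.4 and 27) were highest on replicate 2, F5 (136.7, 106.5 and 17.9) on replicate 1 and Aqp1 (54.4, 65.9 and 101.9) on replicate 3. Second probe sets of Folr1, with 28.8, 92.9 and 22.9, and of Igf2, with 18.9, 19.5 and 13.9, were also not above background on all arrays.

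The choroid plexus list lay 0.63 above its own mean on replicate 2 and 0.56 below on replicate 3. This joint shift of 1.19 exceeded all 10000 matched random lists, whose median was 0.18. Its median SD of 0.53 also exceeded them all, against 0.23 for random lists. It was the only list of 21 apart in spread, the others lying at percentiles 16.4 to 92.2, and that call was lost without replicate 3, with a median SD of 0.31 at percentile 89.4. Without Ttr, an alternative chosen after seeing the data, the other 7 markers had a joint shift of 0.68 at percentile 99.9. Leaving out 1 replicate gave joint shifts of 1.00 without replicate 1, 0.47 without replicate 2 and 0.60 without replicate 3, the lowest at percentile 98.5. The value without replicate 2 includes Ttr, with 1016.6 on replicate 1 and 161.4 on replicate 3. Cox8b, with 152.2 and 326.5, and Kl, chosen after its values were seen, with 203.4 and 243.1, went the other way. The remaining markers above background were higher on replicate 1 than on replicate 3. Leaving out Ttr and replicate 2 together was not run. With the strictest floor, 1 member was left and the list could not be tested.

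**Figure D2:**
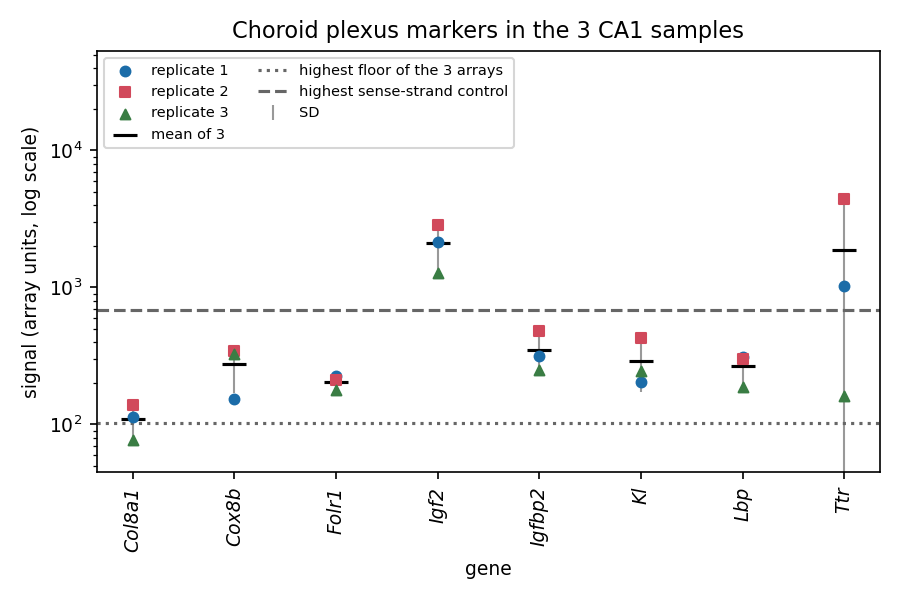
Signal of the 8 choroid plexus markers above background (x axis) on a log scale in array units (y axis), with 1 point per replicate, a bar for the mean, a line for the SD (n = 3, the lower end running off the axis for Ttr), and dotted and dashed lines for the 2 background floors at their highest over the arrays. Every marker is higher on replicate 2 than on replicate 3, and Ttr spans 161.4 to 4441.6.

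The other lists apart in joint shift had shifts that varied with the processing. Synaptic vesicle genes lay 0.09 above their own mean on replicate 1 and 0.11 below on replicate 3, a joint shift of 0.20 at percentile 97.6, with 11 of 14 genes higher on replicate 1 than on replicate 3. The astrocyte markers had a similar profile, 0.08 above their own mean on replicate 1 and 0.11 below on replicate 3. Cplx1, a regulator of vesicle fusion, had 1221.6, 1102.2 and 717.8 on replicates 1, 2 and 3. Syt11 had 650, 823.4 and 488.2, and Rab3a, a vesicle GTPase, had 662.4, 354.2 and 629.1. Snap25, a protein of the fusion complex, had 19920 ± 753, and Syn2, a synapsin, had 1466 ± 77.4. Oxidative phosphorylation genes lay 0.09 below their own mean on replicate 1 and 0.04 above on both replicates 2 and 3, a joint shift of 0.13 at percentile 99.6. Of these 64 genes, 49 were lower on replicate 1 than on replicate 3. Among the members with the largest SD, Ndufa1 went against the list with 186.6, 120.2 and 88.2, as did Atp5j2 with 177.6, 117.9 and 90.9. Cyc1, cytochrome c1, had 13544 ± 49.5, though its second probe set had 2678 ± 496, and Ndufs3 had 3131 ± 45.4. Proteasome genes lay 0.08 below their own mean on replicate 1 and 0.08 above on replicate 3, a joint shift of 0.16 at percentile 98.4, with 24 of 35 genes lower on replicate 1 than on replicate 3.

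Within the proteasome list, Psmb6 had 1138.6, 1794 and 1810.3 on replicates 1, 2 and 3. Psma6 had 3202.9, 3138.5 and 4636, and Psmd12 had 481.9, 498.2 and 722.1. Psmd7 had 1079 ± 27.1 and Psma3 had 5923 ± 170. Without replicate 1, the joint shifts of the synaptic vesicle, oxidative phosphorylation and proteasome lists were 0.12, 0.01 and 0.06, at percentiles 93.2, 15.1 and 87.4. Without replicate 3, the synaptic vesicle list was at percentile 66.4 and the proteasome list at 82.4. The synaptic vesicle list was also lost with all values raised to the floor, at 4.07. The proteasome list was lost with the floor at the 25th percentile, at 90.6, with the strictest floor, at 93.6, and with probe sets chosen by mean signal, at 94.1. Its joint shifts there were 0.11, 0.10 and 0.15 in that order, against 0.16 in the main run. Other settings gave larger joint shifts. The synaptic vesicle list had 0.39 at percentile 99.8 with the floor at the median control and 0.28 at percentile 100 with the strictest floor. With all values raised to the floor, the oxidative phosphorylation list had 0.36 at percentile 99.2 and the proteasome list 0.36 at 99.1. Raised values differ between the arrays as the floors do, 101.8 on replicate 1 and 64 on replicates 2 and 3. Of the 21 lists, 5 passed the threshold for joint shift, where chance gives 1.05 for lists of unrelated genes.

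**Figure D3:**
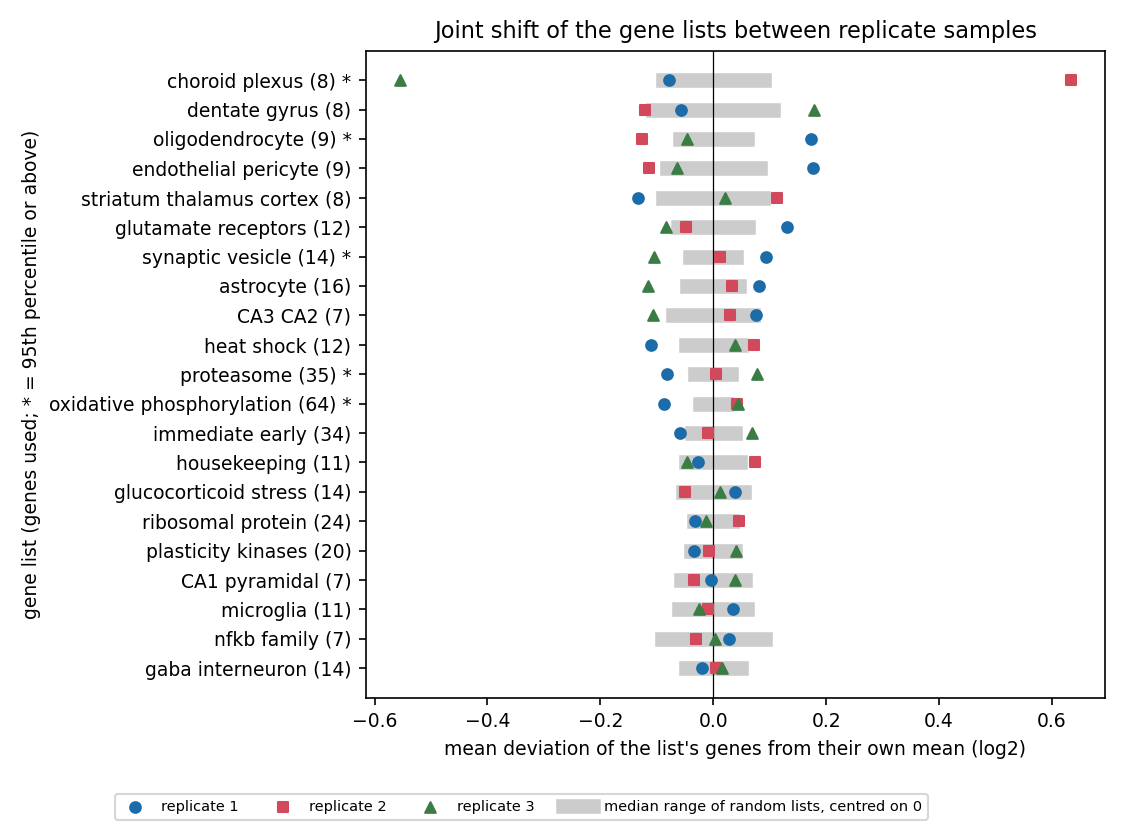
Mean deviation of each list's genes from their own mean, in log2 units (x axis), for the 21 gene lists (y axis, with the number of genes), 1 point per replicate, with grey bars for the median range of matched random lists and a star for lists at the 95th percentile or above. The choroid plexus list spans -0.56 to 0.63, and the next widest, dentate gyrus, spans 0.30.

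Single genes with large differences between replicates were mostly dim. After centring the arrays, a range of over 2-fold was seen in 545 of the 7173 probe sets (7.6%), and 55.6% of these lay in the dimmest of the 5 brightness classes, against 0.55% in the brightest. The direction of these differences depended on how probe sets were chosen, and the floor was higher on replicate 1. Where replicate 1 stood apart from the other two, it was higher in 163 of 216 cases, in 97 of 148 with 1 floor on all arrays and in 222 of 465 with probe sets chosen by mean signal. The 15 genes with the largest SD were Ttr, A4galt, Tyk2, Nsmf, Notch2, Myh7, Ginm1, Fzd9, Scx, Six2, Olfr140, Slc1a6, Wdr5, Shh and Ifna9, and none of them was above the strictest floor on all arrays. After Ttr, the widest range was that of A4galt, a glycosyltransferase, at 8.21-fold, and Tyk2, a Janus kinase, followed at 7.13-fold. A second probe set of Notch2, a Notch receptor, had 134 ± 4.92 and did not vary as the first did, with 401.9, 66.9 and 206.6. The probe sets of Nsmf moved apart too, with 177.6, 830 and 998.9 for one and 215.1, 71 and 188.4 for the other.

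Probe sets of the same gene were compared across genes. For 842 genes with at least a pair of probe sets above background, the median correlation of their deviations over the 3 arrays was 0.044. Random pairings matched on brightness had a median of 0.010 and a 95th percentile of 0.101. Both probe sets were highest on the same replicate for 35.3% of genes, against 33.5% in random pairings. The median correlation was higher in other settings. It was 0.24 for 163 pairs brighter than the median without neighbouring probe set numbers, at percentile 91.4 of random pairings. Those random pairings had a median of 0.075 and a 95th percentile of 0.274. It was 0.10 without centring, 0.109 with the strictest floor, 0.099 with 1 floor on all arrays, 0.080 with the floor at the array median, 0.078 with probe sets chosen by mean signal and 0.196 with all values raised to the floor. Random pairings for these latter settings are not given here, so their values cannot be set against 0.101. Genes are not independent replicates here.

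The control probe sets that gauge RNA quality gave similar ratios on all arrays, each with the 3' end brighter than the 5' end. Whether this lowered the signal of other probe sets was not tested. The ratio of the 3' to the 5' probe set was 4.43 ± 0.098 (SD, n = 3) for Gapdh and 2.91 ± 0.099 for Actb. The labels give male mice. Xist, the RNA of the inactive X chromosome in females, was not above background on any array, with 28.2 ± 15.5. Of the 3 Y-linked genes measured, Uty was above background on all arrays, with 144 ± 39.1. Eif2s3y was above it on replicates 2 and 3 only, with 88.5, 137.4 and 178.4, and Kdm5d was not above it on any array, with 22.8 ± 10.8.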

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

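Some control probe sets, used above at most to set a floor or gauge RNA quality, gave signal above the background floor. Of the 15 control probe sets that read the opposite strand of control transcripts, 13 were above the floor on all 3 arrays. The control probe set for the B1 repeat had a mean signal of 92778 ± 21199 (SD, n = 3), and that for the B2 repeat had 55997 ± 6373.

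The tests in this part were chosen after the results were seen, except that the outcomes of the leptomeninges test and of the test on brighter probe sets were unknown when those were set. The first pattern is the difference in choroid plexus markers between replicates. Noise in the Ttr probe set alone would leave the other markers like matched random lists, but without Ttr the list stayed at percentile 99.85 of matched random lists. Unequal amounts of choroid plexus tissue in the dissections stay open, since the direction of the other markers (7 of 7 higher on replicate 2 than on replicate 3) was already known. Among the markers not above background on all arrays, Slc4a5, Ace, Cldn2 and F5 were also higher on replicate 2 than on replicate 3, while Aqp1 was lower. F5 was highest on replicate 1, as were Lbp and Folr1. The 10 leptomeningeal genes above background differed by 0.12 ± 0.17 (SE over genes) between replicates 2 and 3 on the log2 scale. The choroid plexus list without Ttr differed by 0.68 ± 0.15. These errors describe genes, not samples, and each replicate is a single array, so some meninges cannot be ruled out. The design has a single group, so no biological explanation was tested.

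The second pattern is the 545 probe sets with a range of over 2-fold. Noise of dim probe sets is a candidate explanation that stays open, since the 55.6% in the dimmest of 5 brightness classes is the observation that raised it and does not test it. For probe sets brighter than the median, a difference in RNA would be shared by separate probe sets of one gene. Their median correlation was 0.24 over 163 pairs without neighbouring probe set numbers, at percentile 91.4 of random pairings. The pairs were taken whatever their range, and most of the 545 probe sets were dim. The correlation therefore cannot decide how much of the differences of over 2-fold reflects RNA.

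The third pattern is the small joint shift of 4 lists, oligodendrocyte, synaptic vesicle, oxidative phosphorylation and proteasome. Uneven scaling across brightness was not decided by quantile normalization, after which all 4 lists stayed at the 95th percentile or above. The random lists were already matched on brightness, so uneven scaling would reach them too. After this normalization the joint shifts were 0.30, 0.22, 0.10 and 0.12 in the order given, against 0.30, 0.20, 0.13 and 0.16 without it. Whether a single array decides all 4 stays open: leaving out replicate 1 took 4 of the 4 below the threshold, but leaving out replicate 3 took 2 and leaving out replicate 2 took 1. The oxidative phosphorylation shift lay with replicate 1. It was 0.01 without replicate 1, at percentile 15.1, but 0.14 without replicate 2 and 0.12 without replicate 3, at 99.7 and 99.6. Replicate 1 also had the highest background floor: with 1 floor on all arrays the 4 lists stayed at the 95th percentile or above, but with probe sets chosen by mean signal the oligodendrocyte and proteasome lists did not, at percentiles 90.7 and 94.1. Their joint shifts there, 0.31 and 0.15, were close to the 0.30 and 0.16 of the main run, so these lost calls do not show that the floor made the shifts.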

How the results depend on the processing

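No paired analysis was possible because the study has a single group. The floor at the sense-strand controls, the single floor on all arrays, the choice of probe sets by mean signal, the choroid plexus list without Ttr and the probe pairs without neighbouring numbers were chosen after seeing the data. The number of probe sets above background was 7173 and fell to 2539 with the floor at the highest sense-strand control. The number with a range of over 2-fold, 545, depended on the floor. It was 1835 at the median control, 962 at the 25th percentile, 112 at the array median or with only probe sets above the array median, 7 at the highest sense-strand control, 328 with 1 floor on all arrays, 1216 with probe sets chosen by mean signal, and 1206 with all probe sets raised to the floor. It was 271 to 290 with a replicate left out, since 2 arrays span less than 3. The median SD was 0.19 and became 0.12 at the highest sense-strand control. The median correlation of probe sets of one gene, 0.044, was 0.080 with the floor at the array median or only probe sets above the array median, 0.109 at the highest sense-strand control, 0.099 with 1 floor on all arrays, 0.078 with probe sets chosen by mean signal, 0.10 without centring and 0.196 with all probe sets raised to the floor, where genes below the floor share the same raised values. The 340 list members above background became 208 at the highest sense-strand control. The 1 Y-linked gene above background became 2 at the median control and at the 25th percentile, 0 at the array median and at the highest sense-strand control, and 1 to 2 with a replicate left out. The 1 list apart in spread became 2 with the mean of all probe sets, 0 of 16 lists at the highest sense-strand control, 5 of 23 with values raised to the floor, and 0 to 2 with a replicate left out. The 5 lists apart in joint shift became 2 to 6 with a replicate left out and 3 of 22 with probe sets chosen by mean signal, and stayed at 4 to 6 under the other alternatives. The choroid plexus joint shift passed the threshold in every alternative run that left at least 3 members, at percentiles 98.5 to 100. Leaving out Ttr and a replicate together was not run. For the other lists, 290 of 316 alternative joint shifts kept their side of the threshold, 15 were lost, 11 were gained and 0 turned. All 15 lost belong to the 4 other lists called apart, while most of the 316 come from lists not called apart in the main run. The floor at the array median and the choice of only probe sets above it gave the same values, and both are counted. For all lists, 323 of 331 alternative spreads kept theirs, 1 was lost and 7 were gained. Raising values to the floor took the synaptic vesicle list to percentile 4.07 and the oligodendrocyte list to 13.2, while the oxidative phosphorylation and proteasome joint shifts became 0.36 and 0.36. The floors differ between the arrays, so raised values do too, and how far this explains these values was not tested. Averaging all probe sets of a gene moved the level by more than its SD for 19 of the 22 named genes with several, since dimmer probe sets enter the mean, and quantile normalization did so for 0 of 63. The Gapdh and Actb 3' to 5' ratios, 2.15 and 1.54 in log2, ranged from 2.13 to 2.16 and from 1.53 to 1.57 with a replicate left out. What limits these data is the signal over background, since the floor decides the count of variable probe sets, and the number of arrays.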

Other observations

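Further gene groups were measured in CA1, and the strictest floor was chosen after seeing the data. Of 14 heat shock genes, 12 were above background, and 11 of the 12 were lower on replicate 1 than on replicate 2. Their joint shift of 0.18 was at percentile 91.5 and passed the threshold with the strictest floor, at 98.7. Of 15 microglial genes, 11 were above background, with a joint shift of 0.06 at percentile 17.2. Of 33 ribosomal protein genes, 24 were above background, with a median SD of 0.09 at percentile 16.4 and a joint shift at percentile 61.8. Of 12 housekeeping genes, 11 were above background, with a joint shift at percentile 66.0. Of 7 measured blood cell genes, 2 were above background, too few for a list test. Chosen after their values were seen, these were Hba-a1, alpha globin, with 3030 ± 375, and Hbb-b2, beta globin, with 463 ± 104.

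Among probe sets above the strictest floor on all arrays, 7 had a range of over 2-fold, and all are given here after their values were seen. After centring the arrays, Igf2 ranged over 2.24-fold, Swi5 over 2.25-fold and Tnpo3 over 2.70-fold. Of the other 4, which have no single gene name here, 1 had 7495.7, 12808.8 and 4395.3 on replicates 1, 2 and 3, the order that Ttr followed.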
